A study of Mus musculus with 6 samples.

How the data were processed

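Labelled RNA from mouse embryonic intestine was hybridised to Affymetrix Mouse Gene ST arrays, which hold several probes across each transcript. The 6 samples were 3 Klf5-deleted and 3 control pools of 2 intestines each, at day E14.5, per the labels. The labels give the strain as mixed. Groups and replicate numbers were taken from the sample titles.

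The deposited values were log2 signals made with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. As a method, RMA corrects background, makes the distributions of the arrays alike by quantile normalization and summarises probes per transcript by median polish, so that a shift common to most genes would be removed. The deposited values ranged from 3.51 to 14.3. The genome build and the annotation used for the array are not given in the sources used here, and no coordinates are printed. Arrays have no read depth. Dim genes near the lower end of the range change less on the array than in the tissue, so folds of such genes are understated.

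The table held 35557 rows. Platform annotation gave 21789 rows with 1 gene symbol and 1621 rows with several symbols, and the other 12147 rows are unnamed here. Symbols were updated through gene IDs to RefSeq of assembly GRCm38.p6, where 21698 of the 21789 rows matched, and the other 91 kept the symbol of the annotation. Rows with exactly 1 symbol were kept, and for the 999 genes with more than 1 of them the one with the highest mean over the 6 arrays was used. For 1 of the 999 genes, probe sets passed the test in opposite directions. This gave 19938 genes, with no filter on level. Gene names come from the table of the platform and can be out of date.

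The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, Klf5-deleted minus control), with Benjamini-Hochberg adjustment over the 19938 genes and a threshold of 0.05. Standard errors are those of limma's moderated variance. Gene lists were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, adjusted over 36 lists. The lists, the rule for named genes and the alternatives were fixed before the data were examined. The lists held 710 distinct members, of which 656 were matched, and the other members were not analysed here. The lists covered brush border, digestion and transport, lipid uptake, xenobiotic metabolism, goblet, enteroendocrine and Paneth cells, epithelial transcription factors, stem cells, Wnt, Hedgehog, PDGF and villus cluster, BMP, Notch, FGF and EGF signalling, pan-epithelial genes, desmosomes and keratins, tight junctions, smooth muscle, enteric neurons and glia, endothelium, red cells, leukocytes, mesothelium, fibroblasts, proliferation, the Klf and Sp family, stomach and esophagus, pancreas, liver, gut position, cholesterol synthesis, stress genes, p53 targets, interferon, and Y-linked and X-inactivation genes. Named were Klf5, the 12 largest falls and the 12 largest rises among genes past the threshold whose groups did not overlap (predicted-gene names left out), and up to 4 members of each list with the smallest p. Genes outside the rule are marked as chosen after their values were seen.

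The pipeline was tested on simulated data: normal values for the 19938 genes with their means and spreads, in which 200 genes were changed. In this simulation of 3 arrays against 3, limma recovered 14.0% of the changes of 0.25 on the log2 scale, 80.0% of those of 0.5, 98.0% of those of 1 and 100% of those of 2, and 3.31% of its calls were false. The simulated list of 20 genes shifted by 0.5 was recovered by camera, and 0 of 35 unshifted lists were called. The simulation drew genes independently. It changed 200 genes, whereas 3496 genes were called in the data. The Benjamini-Hochberg cutoff depends on how many genes change, so the shares recovered in the data can differ, above all for small changes. No columns of other samples were in the table. The submitters describe each sample as a pool of intestines, and whether the pools came from separate litters is not given in the sources used here, so the p values measure the spread between these pools.

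Alternatives were each of the 6 arrays left out in turn, the replicate number as a block, quantile normalization over all rows, centring on the array median, the lowest 25% or 50% of genes left out, an intensity trend with robust variance (in camera the trend alone), array weights, the mean of all probe sets of a gene, all rows tested on their own, and a threshold of 0.1. The male share of each pool as a covariate was added after the data were seen. It was computed from the linear signals of Eif2s3y, Kdm5d and Uty, with 0% set at the lowest array and 100% at the mean of the Klf5-deleted arrays.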

Results

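Gene expression was measured in the intestine of mouse embryos at day E14.5, before villi form. Klf5-deleted embryos were compared with control embryos that were wild-type for Klf5 and carried the ShhEGFP/Cre allele. Klf5 encodes a zinc-finger transcription factor of epithelia. Each group held 3 arrays, and each array was hybridised with labelled RNA from a pool of 2 intestines, taken about 1.5 cm anterior to the cecum. The values were log2 signals that the authors had normalised with RMA. The medians over all rows were 7.85, 7.87 and 7.89 in Klf5-deleted replicates 1 to 3 and 7.87, 7.87 and 7.81 in control replicates 1 to 3. Across all rows, pairs of arrays correlated at 0.994 to 0.997 within a group (6 pairs) and at 0.989 to 0.993 between groups (9 pairs). These correlations are across rows, which are not independent replicates. The first principal component held 70.9% of the variance over genes and separated the Klf5-deleted arrays (−23.7, −17.4 and −17.1) from the controls (18.8, 21.3 and 18.2). The number of arrays limits the precision of each value.

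The comparison addressed which genes change without KLF5 before villus formation, as candidates for genes that KLF5 regulates. Klf5 itself read 10.2, 10.5 and 10.3 in the Klf5-deleted arrays and 11.5, 11.7 and 11.8 in the controls. Its signal fell by 1.33 on the log2 scale (SE 0.08, n = 3 arrays per group, adjusted p = 9.62e-05 with limma), to 39.8% of the control level. The exact two-sided permutation test gave p = 0.1 for Klf5, the smallest value that 3 arrays against 3 allow. Which exons were deleted is not given in the sources used here, and probes outside the deleted part would still read the remaining transcript.

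Members of absorptive epithelial gene lists fell in the Klf5-deleted intestine: 14 of 19 for the brush border, 11 of 25 for digestion and transport, 11 of 23 for lipid uptake and 13 of 32 for xenobiotic metabolism. So did 11 of 18 tight junction genes and 15 of 23 epithelial transcription factor genes, Elf3 and Hnf4a among them. Camera called these lists lower with its preset correlation, and none of them with an estimated correlation (adjusted p = 0.193 to 0.328). Genes that rose included members of the Hedgehog pathway and mesothelial genes. Of 19938 genes tested, 3496 passed a Benjamini-Hochberg adjusted p of 0.05, of which 1785 rose and 1711 fell. At larger sizes falls outnumbered rises: 225 genes fell and 18 rose at least 2-fold, and 44 genes fell and 0 rose at least 4-fold. The groups did not overlap for 7181 genes, against 10% of genes by chance for 3 arrays against 3. The median log2 fold change over all genes was 0.02. Without control replicate 2, 2000 genes passed, 868 of them higher and 1132 lower. With the male share of the pools as a covariate, an alternative added after the data were seen, 84 genes passed (4 higher and 80 lower). In that fit the median SE was 2.48 times as large, and 3465 of the 3496 genes kept their sign, with a median of 1.03 times their log2 fold change. With the lowest 50% of genes left out, 151 genes passed the threshold and 2-fold, against 243. The number of genes higher was 1174 without Klf5-deleted replicate 3 and 1143 without control replicate 3. The Klf5-deleted arrays also differed from the controls in the sex of the pooled embryos. Xist, the RNA that silences an X chromosome in female cells, fell by 5.99 on the log2 scale (SE 0.20, adjusted p = 8.14e-06), with 5.89 to 6.47 in the Klf5-deleted arrays and 11.9 to 12.6 in the controls. Xist also kept its call with the male share as covariate, so the signs kept in that fit do not separate sex from Klf5.

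Among the genes with the largest falls, Lgals4, which encodes the intestinal lectin galectin-4, fell 18.3-fold (log2 fold change −4.20, SE 0.20, adjusted p = 3.46e-05). Close paralogs of Lgals4 can share its probes, so this value is uncertain as to the copy. Cps1, the mitochondrial enzyme that makes carbamoyl phosphate for citrulline synthesis, fell 16.3-fold (log2 fold change −4.03, SE 0.15, adjusted p = 1.36e-05). The potassium channel subunit Kcne3 fell 11.6-fold and Eps8l3, a relative of the actin-capping protein EPS8, fell 10.5-fold. Elf3, an ETS transcription factor of epithelia, fell 9.70-fold. The mucosal scavenger receptor gene Dmbt1 fell 8.95-fold, the gluconeogenic enzyme gene Fbp2 8.64-fold, and the intestinal surface antigen gene Gpa33 8.0-fold. Clca3b fell 7.99-fold, Trim31 7.59-fold and the intestinal fatty acid binding protein gene Fabp2 6.85-fold, and Clca3b belongs to a family of close paralogs. The adjusted p values of these genes from Kcne3 to Fabp2 were at most 0.00197, with SE between 0.05 and 0.39 on the log2 scale.

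The largest rise was that of Hsd3b6, a hydroxysteroid dehydrogenase, at 3.92-fold (log2 fold change 1.97, SE 0.49, adjusted p = 0.0324). Its call was lost without control replicate 1 (1.87, adjusted p = 0.0941) and without control replicate 2 (1.75, adjusted p = 0.111). Nepn rose 3.45-fold (SE 0.39 on the log2 scale, adjusted p = 0.0204), and its call was lost without Klf5-deleted replicate 3 (1.65, adjusted p = 0.0688) and without control replicate 1 (1.75, adjusted p = 0.0623), 2 (1.82, adjusted p = 0.0626) or 3 (1.78, adjusted p = 0.0694). Rfx6, a transcription factor of endocrine progenitors, rose 3.21-fold (log2 fold change 1.68, SE 0.16, adjusted p = 0.000565). Clvs2 rose 2.48-fold, Akr1c18, a steroid-reducing enzyme gene, 2.46-fold, and the adenylate cyclase gene Adcy8 2.39-fold. The collagen prolyl hydroxylase gene P4ha3 rose 2.34-fold, Pnliprp1 2.33-fold, the glucose transporter gene Slc2a3 2.24-fold, the carbonic anhydrase gene Car14 2.22-fold, Ambp 2.15-fold and Emb 2.14-fold. Adjusted p was at most 0.00873 for the genes from Clvs2 to Emb.

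Of the 19 measured genes of brush border structure and adhesion, 14 fell and 1 rose (15 fell and 2 rose when adjusted over the list alone), with a median log2 fold change of −1.21. Besides Eps8l3, the microvillus motor genes Myo1a and Myo1d fell by 1.77 (SE 0.07) and 1.38 (SE 0.06), and Eps8 fell by 1.21 (SE 0.05). The gene that rose was Mpp1 (0.23, SE 0.05), a membrane scaffold gene chosen for mention after its values were seen. Its call was lost without Klf5-deleted replicate 2 (0.21, adjusted p = 0.0614) and without control replicate 1 (0.20, adjusted p = 0.0626) or 2 (0.22, adjusted p = 0.0739). The list was called lower by camera with its preset correlation (adjusted p = 9.04e-14), and not with an estimated correlation (adjusted p = 0.193). Of the 25 measured genes of digestive enzymes and nutrient transporters, 11 fell and 0 rose (12 fell when adjusted over the list alone), with a median of −0.21. The glucose transporter gene Slc5a1 fell by 2.28 (SE 0.09), and the peptidase genes Xpnpep2, Anpep and Enpep fell by 1.87 (SE 0.12), 1.38 (SE 0.07) and 0.86 (SE 0.06). The camera test gave adjusted p = 5.96e-07, and adjusted p = 0.328 with an estimated correlation. Of the 23 measured genes of lipid uptake and lipoprotein assembly, 11 fell and 0 rose, also when adjusted over the list alone, with a median of −0.23. With Fabp2, Mttp, which loads lipid onto nascent lipoproteins, fell by 1.87 (SE 0.06), and the triglyceride synthesis genes Mogat2 and Dgat2 fell by 1.81 (SE 0.09) and 1.15 (SE 0.06). This list had adjusted p = 2.25e-07 by camera, and adjusted p = 0.328 with an estimated correlation. Among 32 genes of xenobiotic and retinoid metabolism, 13 fell and 2 rose (15 fell and 3 rose when adjusted over the list alone), with a median of −0.23. The nuclear receptor gene Nr1i2 fell by 2.22 (SE 0.10), the cytochrome gene Cyp2s1 by 2.11 (SE 0.05), the alcohol dehydrogenase gene Adh1 by 2.08 (SE 0.12) and Gstm3 by 1.68 (SE 0.09). Camera called this list lower (adjusted p = 6.25e-06), and not with an estimated correlation (adjusted p = 0.323). Over the same arrays the pan-epithelial list had a median of −0.85.

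**Figure D1:**
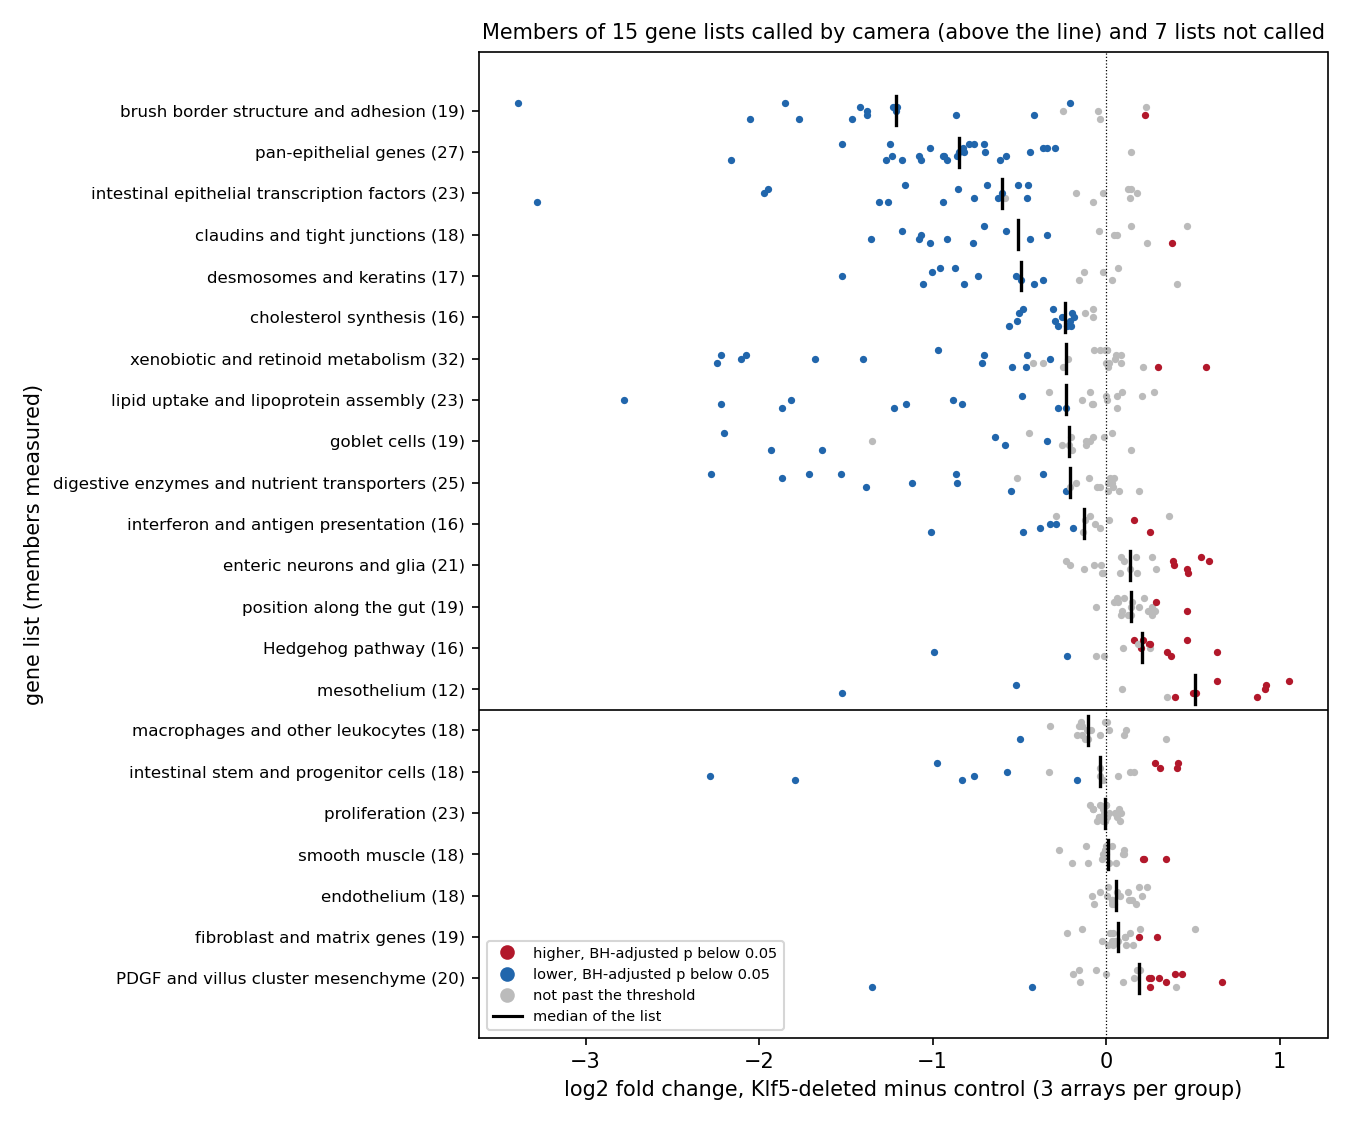
Each point is the log2 fold change (x axis, Klf5-deleted minus control, 3 arrays per group) of a measured member of a gene list (y axis, with the number of members), coloured by its Benjamini-Hochberg call, and the black bar is the median of the list. The brush border list has a median of −1.21 and the pan-epithelial list −0.85, while the proliferation list lies within −0.09 to 0.09.

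Of 27 genes used by epithelia of many organs, the pan-epithelial list, 26 fell and 0 rose, also when adjusted over the list alone, with a median of −0.85. Krt19 fell by 1.52 (SE 0.08), Bspry by 1.25 (SE 0.08), the junction gene Tjp3 by 1.18 (SE 0.08) and the protease inhibitor gene Spint2 by 0.85 (SE 0.06). The member that did not pass was Cldn6 (0.15, SE 0.07), chosen for mention after its values were seen. Camera gave adjusted p = 1.37e-24, and adjusted p = 0.193 with an estimated correlation. Of 17 desmosome and keratin genes, 11 fell and 0 rose, also when adjusted over the list alone, with a median of −0.49. Pkp2, a desmosomal plaque gene, fell by 1.05 (SE 0.08), Krt7 by 0.96 (SE 0.07) and Krt23 by 0.87 (SE 0.06). This list had adjusted p = 5.12e-09, and adjusted p = 0.193 with an estimated correlation. Of 18 claudin and tight junction genes, 11 fell and 1 rose (11 fell and 3 rose when adjusted over the list alone), with a median of −0.51. Ocln, Cldn3 and Cldn7 fell by 1.08 (SE 0.08), 1.07 (SE 0.08) and 1.01 (SE 0.10). The rise was that of Cldn1 (0.38, SE 0.09), chosen for mention after its values were seen. Its call was kept without Klf5-deleted replicate 3 and lost without Klf5-deleted replicate 1 (0.34, adjusted p = 0.0732) or 2 (0.31, adjusted p = 0.0769) and without control replicate 1 (0.42, adjusted p = 0.0521), 2 (0.38, adjusted p = 0.0888) or 3 (0.34, adjusted p = 0.10). Camera gave adjusted p = 5.09e-05, and adjusted p = 0.193 with an estimated correlation. The lists share members: Krt19 is also in the desmosome and keratin list and in the mesothelial list, and Tjp3, Ocln, Cldn3 and Cldn7 are in both the pan-epithelial and the tight junction list.

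Of 23 intestinal epithelial transcription factor genes, 15 fell and 0 rose (17 fell and 1 rose when adjusted over the list alone), with a median of −0.60. After Elf3 (log2 fold change −3.28, SE 0.11), the nuclear receptor genes Hnf4a and Hnf4g, which drive enterocyte genes, fell by 1.97 (SE 0.08) and 1.95 (SE 0.12), and Gata5 fell by 1.31 (SE 0.08). The intestinal identity factors Cdx1 and Cdx2 fell by 0.94 (SE 0.08) and 0.62 (SE 0.08). Foxa1 (0.18, SE 0.09) and Klf4 (−0.02, SE 0.05), the latter a related Krüppel-like factor, did not pass, and without Klf5-deleted replicate 1 Foxa1 passed (0.28, adjusted p = 0.0159). Gata4 fell by 0.45 (SE 0.07). Cdx1, Cdx2, Gata4, Foxa1 and Klf4 were chosen for mention after their values were seen. The list was called lower by camera (adjusted p = 1.81e-11), and not with an estimated correlation (adjusted p = 0.193). Among the 23 measured Klf and Sp family genes other than Klf5, 3 fell and 1 rose (3 and 3 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.902). Klf3 fell by 0.35 (SE 0.06).

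**Figure D2:**
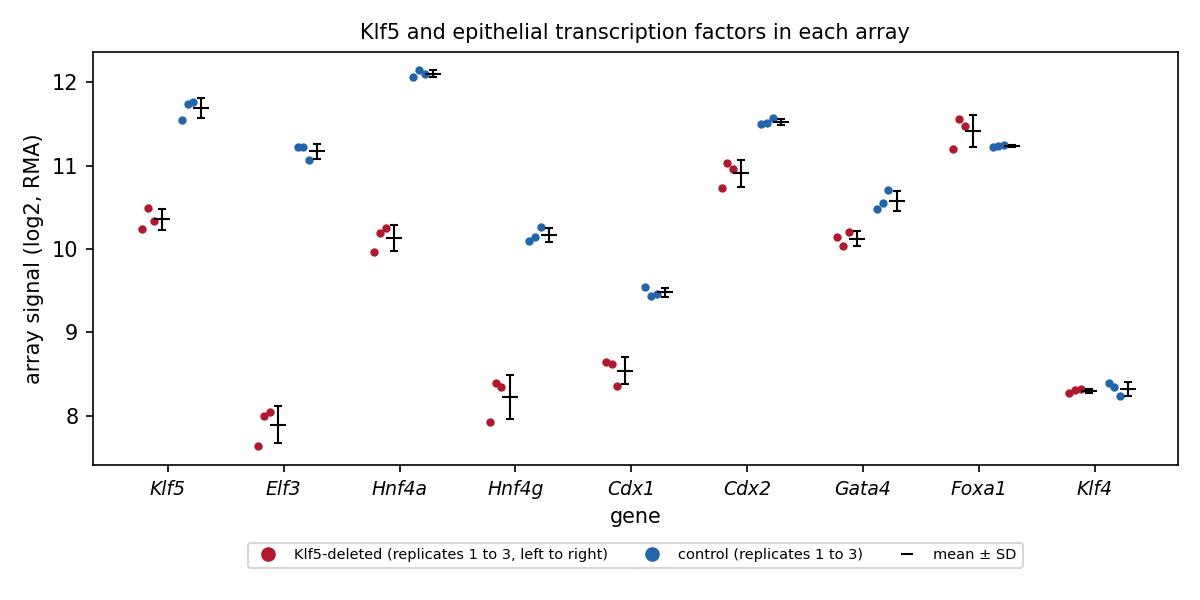
Points show the array signal (y axis, log2, RMA) of Klf5 and 8 epithelial transcription factor genes (x axis) in the 3 Klf5-deleted and 3 control arrays, with mean ± SD beside them. Klf5, Elf3, Hnf4a, Hnf4g, Cdx1, Cdx2 and Gata4 do not overlap between the groups, whereas Foxa1 and Klf4 did not pass the test.

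Of 19 goblet cell genes, 6 fell and 0 rose (10 fell when adjusted over the list alone), with a median of −0.21. Atoh1, the transcription factor that specifies secretory cells, fell by 1.93 (SE 0.13), Muc13 fell by 2.20 (SE 0.28), the trefoil peptide gene Tff3 by 1.64 (SE 0.12) and Galnt12 by 0.64 (SE 0.08). The goblet mucin gene Muc2 (−0.01, SE 0.05) did not pass and was chosen for mention after its values were seen. Camera called this list lower (adjusted p = 3.16e-06), and not with an estimated correlation (adjusted p = 0.328). With the lowest 50% of genes left out it did not pass either (adjusted p = 0.0757), with a median of −1.49 over the members kept. Of 25 enteroendocrine genes, 2 rose and 2 fell (2 and 3 when adjusted over the list alone), and the list was not called (adjusted p = 0.664). Neurog3, the factor that starts endocrine differentiation, fell by 1.66 (SE 0.28), while Rfx6, which acts after it, rose as given above, and Cpe rose by 0.57 (SE 0.08). Of 9 genes of Paneth cells, which arise after birth, 3 fell and 1 rose, also when adjusted over the list alone, and the list was not called (adjusted p = 0.545). The pentraxin gene Mptx1 was at 0.36 (SE 0.07, adjusted p = 0.0132). Lyz1, Defa24 and Ang4 were at −0.72 (SE 0.16), −0.35 (SE 0.09) and −0.27 (SE 0.08). Each of these 3 falls lost its call in 4 of the 6 fits leaving out an array.

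Of 18 stem and progenitor genes, 7 fell and 4 rose (8 and 5 when adjusted over the list alone). The Wnt-responsive stem cell genes Ascl2, Lgr5 and Rnf43 fell by 2.28 (SE 0.12), 1.79 (SE 0.22) and 0.97 (SE 0.09), and Myc and Sox9 fell by 0.83 (SE 0.05) and 0.76 (SE 0.07). Camera did not call the list (adjusted p = 0.0823), except without Klf5-deleted replicate 1 (adjusted p = 0.0244) and with the male share as covariate (adjusted p = 0.0310), and fry passed it (adjusted p = 0.00279). Of 22 Wnt targets and feedback genes, 5 fell and 3 rose (5 and 5 when adjusted over the list alone), and Axin2 fell by 0.45 (SE 0.05). The Wnt list was not called (adjusted p = 0.595). Of 23 proliferation genes, 0 passed limma's test at an adjusted p of 0.05, also when adjusted over the list alone, and their log2 fold changes lay between −0.09 and 0.09. Mki67 was at 0.08 (SE 0.04) and Plk1 at −0.09 (SE 0.04).

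Of 16 Hedgehog pathway genes, 9 rose and 2 fell (11 and 2 when adjusted over the list alone), with a median of 0.21. The genes that fell were the epithelial ligand genes Ihh (−0.99, SE 0.10) and Shh (−0.23, SE 0.06), the latter chosen for mention after its values were seen. The Shh call was lost on leaving out any of the 6 arrays: Klf5-deleted replicate 1 (−0.23, adjusted p = 0.0648), 2 (−0.21, adjusted p = 0.0946) or 3 (−0.23, adjusted p = 0.0856), or control replicate 1 (−0.25, adjusted p = 0.0511), 2 (−0.25, adjusted p = 0.0644) or 3 (−0.17, adjusted p = 0.0789). The mesenchymal genes Hhip, a target and inhibitor of the pathway, Boc, a co-receptor gene, and Gli3 rose by 0.64 (SE 0.06), 0.47 (SE 0.08) and 0.37 (SE 0.06). Camera called the Hedgehog list higher (adjusted p = 0.00472), and not with an estimated correlation (adjusted p = 0.193). With the male share as covariate it did not pass either (adjusted p = 0.108), with a median of 0.25. Of 20 genes of PDGF signalling and villus cluster mesenchyme, 8 rose and 2 fell (10 and 4 when adjusted over the list alone). Pdgfc rose by 0.67 (SE 0.06) and Twist2 by 0.44 (SE 0.06), whereas Bmp2 fell by 1.35 (SE 0.13) and Pdgfa, an epithelial PDGF ligand gene, by 0.42 (SE 0.06). Camera did not call the list (adjusted p = 0.0878), except without Klf5-deleted replicate 2 (adjusted p = 0.0261) and with quantile normalization (adjusted p = 0.0371), and the directional test of fry passed it (adjusted p = 0.0111). Of 22 BMP pathway genes, 4 rose and 1 fell, also when adjusted over the list alone, and Chrdl1, a BMP antagonist gene, rose by 0.42 (SE 0.06). Of 21 Notch pathway genes, 4 rose and 2 fell (4 and 4 when adjusted over the list alone), with Lfng at −0.65 (SE 0.06) and Notch2 at 0.49 (SE 0.06). Of 23 genes of FGF and EGF receptor signalling, 7 rose and 6 fell, also when adjusted over the list alone. Spry2 and Fgfr1 rose by 0.50 (SE 0.05) and 0.32 (SE 0.05), and the epithelial receptor genes Fgfr4 and Fgfr3 fell by 0.74 (SE 0.11) and 0.47 (SE 0.05). The BMP, Notch and FGF and EGF lists were not called by camera (adjusted p = 0.443, 0.786 and 0.840), and fry passed the FGF and EGF list (adjusted p = 0.0319).

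Of 12 mesothelial genes, 8 rose and 2 fell (9 and 2 when adjusted over the list alone), with a median of 0.51. Upk1b rose by 0.92 (SE 0.12) and the retinoic acid synthesis gene Aldh1a2 by 0.52 (SE 0.07). The 2 genes that fell were Krt19, which is also epithelial, and Msln (−0.52, SE 0.08). Camera called the mesothelial list higher (adjusted p = 0.0197), and not without Klf5-deleted replicate 1 (median 0.44, adjusted p = 0.0609), with the lowest 50% of genes left out (median 0.52, adjusted p = 0.0629) or with an estimated correlation (adjusted p = 0.571), and fry did not pass it (adjusted p = 0.177). Of 21 genes of enteric neurons and glia, 6 rose and 0 fell (9 and 1 when adjusted over the list alone). Gfra1, Sox10 and Hand2, genes of neural crest derivatives and of gut mesenchyme, rose by 0.47 (SE 0.05), 0.39 (SE 0.07) and 0.38 (SE 0.05). This list passed narrowly (adjusted p = 0.0392). It did not pass without Klf5-deleted replicate 2 (adjusted p = 0.153), without control replicate 1 (adjusted p = 0.129), with the array medians centred (adjusted p = 0.0550), with the lowest 25% or 50% of genes left out (adjusted p = 0.0522 and 0.109), with array weights (adjusted p = 0.0519), with the male share as covariate (median 0.015, adjusted p = 0.885) or with an estimated correlation (adjusted p = 0.722), and fry did not pass it (adjusted p = 0.101). Of 18 smooth muscle genes, 3 rose and 0 fell (3 and 1 when adjusted over the list alone), and Myocd, which drives smooth muscle genes, rose by 0.35 (SE 0.05). Of 19 fibroblast and matrix genes, 2 rose and 0 fell, also when adjusted over the list alone, with Fn1 up by 0.29 (SE 0.05). Of 18 leukocyte genes, 1 fell, Lyz2 (−0.50, SE 0.10), also when adjusted over the list alone, and its call was lost without control replicate 1 (−0.48, adjusted p = 0.0514) or 2 (−0.44, adjusted p = 0.0555). Of 18 endothelial genes, 0 passed limma's test, also when adjusted over the list alone, and Kdr had the lowest p of them (0.21, SE 0.07, adjusted p = 0.0972). The smooth muscle, fibroblast, leukocyte and endothelial lists were not called by camera (adjusted p = 0.693, 0.10, 0.204 and 0.343). Without Klf5-deleted replicate 2 the endothelial list (adjusted p = 0.00161) and the fibroblast list (adjusted p = 0.0423) were called higher, and without Klf5-deleted replicate 1 the leukocyte list was called lower (adjusted p = 0.0210). The fibroblast list was also called higher with quantile normalization (adjusted p = 0.0264) and with an intensity trend and robust variance (adjusted p = 0.0417).

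Of 16 cholesterol synthesis genes, 13 fell and 0 rose, also when adjusted over the list alone, with a small median of −0.24. Stard4, Lss, Insig1 and Fdps fell by 0.56 (SE 0.05), 0.50 (SE 0.06), 0.48 (SE 0.07) and 0.28 (SE 0.04). Camera gave adjusted p = 1.37e-09, and adjusted p = 0.193 with an estimated correlation. Of 16 interferon and antigen presentation genes, 6 fell and 2 rose (7 and 3 when adjusted over the list alone), with a median of −0.13. Cd74, the invariant chain of MHC class II, fell by 1.01 (SE 0.18), and Irf1 and Tapbp fell by 0.48 (SE 0.05) and 0.29 (SE 0.04). This list had adjusted p = 0.00973 by camera, and adjusted p = 0.412 with an estimated correlation. It also did not pass with the lowest 50% of genes left out (median −0.091, adjusted p = 0.109) or with the male share as covariate (median −0.071, adjusted p = 0.266). Of 19 genes that mark position along the gut, 2 rose and 0 fell (1 rose when adjusted over the list alone), with a median of 0.14. The Hox gene Hoxb7 rose by 0.46 (SE 0.05). Camera called this list higher (adjusted p = 0.00472), and not with the lowest 50% of genes left out (median 0.22, adjusted p = 0.0638) or with an estimated correlation (adjusted p = 0.720), and fry did not pass it (adjusted p = 0.101).

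Further lists were not called. Of 17 p53 target and apoptosis genes, 3 rose and 3 fell, also when adjusted over the list alone. Trp53inp1 rose by 0.58 (SE 0.06) and Tnfrsf10b by 0.52 (SE 0.09), and Perp, which is also a desmosomal gene, fell by 0.86 (SE 0.15). Of 20 immediate early and stress genes, 3 fell and 0 rose, and 0 passed when adjusted over the list alone. Of 25 stomach and esophagus genes, 5 fell and 0 rose, also when adjusted over the list alone, with Cldn18 down by 0.77 (SE 0.10) and Muc1 by 0.60 (SE 0.11). Of 15 pancreas genes, 1 rose, also when adjusted over the list alone, and it was Pnliprp1. Of 18 liver genes, 2 rose and 1 fell, also when adjusted over the list alone: Ambp and Rbp4 (0.92, SE 0.14) rose and Cps1 fell. The camera adjusted p was 0.594 for the p53, stomach and liver lists, 0.603 for pancreas and 0.693 for the stress list, and without Klf5-deleted replicate 1 the liver list was called higher (adjusted p = 0.0234). Of 9 red cell genes, 2 rose and 1 fell (3 and 1 when adjusted over the list alone), and the list was not called (adjusted p = 0.594). The transferrin receptor gene Tfrc fell by 0.90 (SE 0.07). The embryonic globin gene Hba-x rose by 0.89 (SE 0.21, adjusted p = 0.0262) and Hbb-y by 0.48 (SE 0.12, adjusted p = 0.0287). The Hba-x call was lost without Klf5-deleted replicate 1 (0.89, adjusted p = 0.0548) or 3 (0.71, adjusted p = 0.0663) and without control replicate 1 (0.90, adjusted p = 0.0694) or 2 (0.72, adjusted p = 0.0804). The Hbb-y call was lost without Klf5-deleted replicate 3 (0.38, adjusted p = 0.0767) and without control replicate 1 (0.47, adjusted p = 0.0803) or 2 (0.39, adjusted p = 0.0888).

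Of the 4 measured genes that report sex, 1 fell, Xist (1 fell and 3 rose when adjusted over the list alone), and the list was not called (adjusted p = 0.976). The Y-linked gene Eif2s3y read 10.3, 10.3 and 10.1 in the Klf5-deleted arrays, 5.38 in control replicate 1, and 9.32 and 8.84 in control replicates 2 and 3. Kdm5d and Uty read 6.62 and 4.93 in control replicate 1. None of the 3 Y-linked genes passed limma's test over all genes (adjusted p = 0.0724 to 0.135). On the X chromosome 133 of 739 genes passed (18.0%), and on the autosomes 3359 of 19106 (17.6%), and these shares did not differ by Fisher's exact test (two-sided p = 0.768). The directions did: 95 of the 133 X-linked genes that passed were higher (71.4%), against 1688 of the 3359 autosomal genes (50.3%; Fisher's exact test over genes, which are not independent, two-sided p = 1.36e-06).

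**Figure D3:**
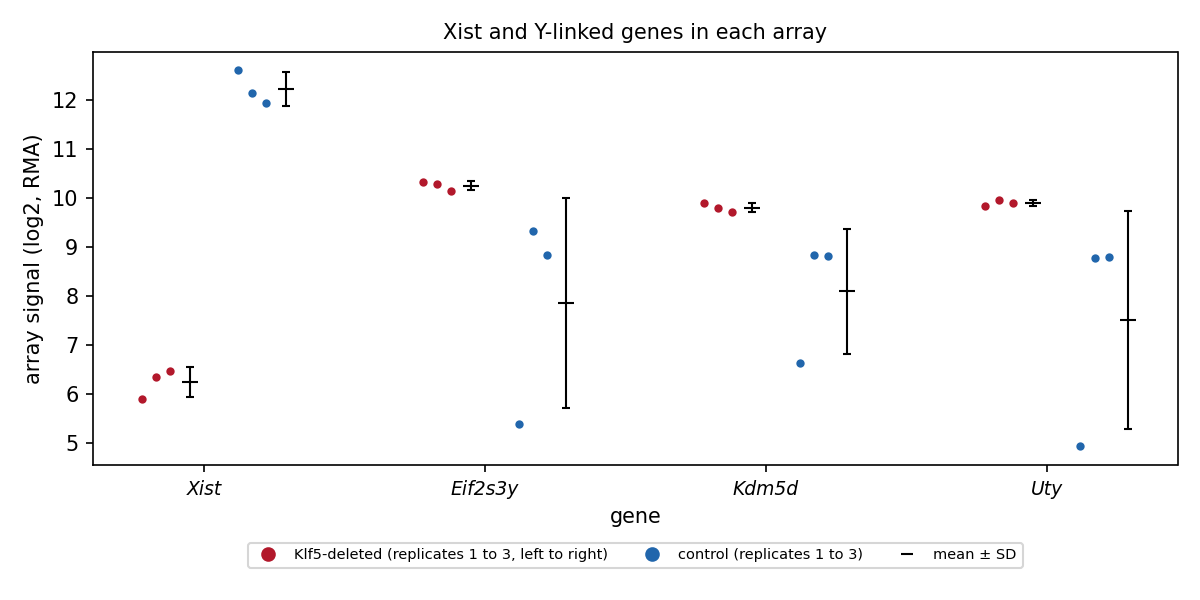
Points show the array signal (y axis, log2, RMA) of Xist and 3 Y-linked genes (x axis) in the 3 Klf5-deleted and 3 control arrays, with mean ± SD beside them. Xist is at 5.89 to 6.47 in the Klf5-deleted arrays and 11.9 to 12.6 in the controls, and Eif2s3y is at 5.38 in control replicate 1.

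Over all 36 lists, camera with a preset correlation of 0.01 called 15, of which 11 were lower and 4 higher, and with an estimated correlation it called 0 (lowest adjusted p = 0.193, with 7 lists at an unadjusted p under 0.05). The directional test of fry, which does not compare a list with other genes, passed 16 lists, 12 of them among the 15. The sign of the median, the mean or a test differed within the enteroendocrine, Wnt, Klf and Sp, stomach, liver, and Y-linked and X-inactivation lists, none of which camera called.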

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

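The tests of rows outside the gene comparison were planned as part of testing all rows on their own, and no test here was chosen after the result was seen. Groups of 3 arrays were not tested for outlying arrays. Rows left out of the gene comparison also held differences between the groups. When all 35557 rows were tested on their own with limma, 58 of the 1621 rows that name several genes passed an adjusted p of 0.05 (3.58%), 19 higher and 39 lower. Of the 12147 rows with no gene name here, 233 passed (1.92%), 136 higher and 97 lower. No explanation was tested for these rows.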

How the results depend on the processing

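The male share of the pools was added as a covariate after the data were seen, and the other alternatives were planned. Klf5 stayed lower and past the threshold in all 16 alternatives (log2 fold change −1.64 to −1.27, adjusted p 7.30e-06 to 0.0334), and in the 6 fits leaving out an array it was −1.40 to −1.27. Leaving out an array in turn gave 2000 to 2757 genes past the threshold, 868 to 1363 higher, 1132 to 1394 lower, 216 to 276 past 2-fold as well, and 14 to 17 gene lists. The lowest count came without control replicate 2. Of those 2000 genes, 1961 were among the 3496, with 0 in the opposite direction. With the male share as covariate 84 genes passed, 4 higher and 80 lower, and 79 of them changed at least 2-fold. The group and the male share overlap in the design, and the median SE was 2.48 times that without it. Xist also passed in that fit, so the covariate does not take out sex. With the lowest 50% of genes left out, 9969 genes were tested and 3599 passed, 151 of them also 2-fold. Genes left out could not be counted, and the filter does not change the fold changes of the others. Of the named genes still tested, 105 kept the same result and 6 gained a call. Camera with an estimated correlation called 0 lists. The list of Y-linked and X-inactivation genes, not called by camera, was called lower by fry although its median was 2.05 and its mean 0.13 (the cause was not tested), and with the male share its median was −3.48. Also with the male share, Pgc was at 0.020 and Eif2s3y at −3.40, where the covariate is made from Eif2s3y itself. Of 130 named genes past the threshold, 26 passed in every alternative run, 74 lost their call with the male share alone (all 74 kept their sign, at a median of 0.952 times their log2 fold change), and 28 lost it on leaving out at least 1 array. The list of enteric neurons and glia lost its call in 9 of 17 alternatives. Centring on the array median gave 56.6% of calls higher, against 51.1%.

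A replicate block, with the replicate number of the titles, gave 2008 genes past the threshold, 900 higher and 1108 lower, and changed the call of 0 of the 36 lists. Deviations from the group means over genes correlated at −0.14, −0.27 and −0.03 between arrays of the same number. No array correlated best with the array of its own number, so these values gave no sign that the numbers pair the arrays. Array signal over background limits genes near the lower end of the range.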

Other observations

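The inflammasome, citrulline, galectin and axon guidance groups, and the tests of sex, tissue share, blood and age and of the splits of gene counts, were chosen after the results were seen. The split test of gene lists was written before. The counts of these groups, drawn up from the values, are no independent evidence, and no enrichment was tested. Of 9 measured genes of the NAIP-NLRC4 inflammasome, which senses bacterial flagellin and secretion systems, 6 fell and 0 rose. Nlrc4 fell by 2.71 (SE 0.08), and Naip5, Naip6 and Naip2, close paralogs whose probes can be shared, were at −2.52 (SE 0.09), −2.49 (SE 0.12) and −2.46 (SE 0.10). The adaptor gene Pycard fell by 1.69 (SE 0.11). Gsdmd fell by 0.40 (SE 0.05). Casp1, the protease of the complex, was at 0.04 (SE 0.08), with signals of 5.00 to 5.31, Casp4 at 0.02 (SE 0.06) and Il18 at 0.30 (SE 0.12). Of 8 measured genes of citrulline and arginine synthesis, 7 fell. After Cps1, Otc fell by 2.47 (SE 0.14), the mitochondrial ornithine carrier gene Slc25a15 by 1.03 (SE 0.08), Aldh18a1 by 0.67 (SE 0.05), Oat by 0.50 (SE 0.09) and Asl by 0.48 (SE 0.07).

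Of 10 genes of galectins and related proteins, 5 fell and 0 rose. Besides Lgals4 they were Lgals3bp (−1.78, SE 0.07), which encodes a galectin-binding protein, Lgals9 (−1.52, SE 0.10), Lgals2 (−0.99, SE 0.14) and Lgals12 (−0.95, SE 0.07). Lgals1 was at 0.04 (SE 0.04). Of 45 axon guidance ligand and receptor genes, 21 rose and 2 fell, with a median of 0.16. This group held called genes alone when it was drawn up and was then replaced by members of gene families, called or not. The families are not complete in it, as Ephb2 is missing, so the counts hold for the listed genes alone. Epha3 rose by 0.87 (SE 0.14), Efnb2 by 0.60 (SE 0.05) and Sema3d by 0.56 (SE 0.05), and Sema3b and Epha2 fell by 0.94 (SE 0.06) and 0.25 (SE 0.05).

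The Klf5-deleted pools and the controls differed in sex as well as in Klf5. From the Y-linked genes, the male share was 46.6% and 41.5% in control replicates 2 and 3, with control replicate 1 at 0 and the mean of the Klf5-deleted arrays at 100 by construction. A test took log2 signals to follow the male share in a straight line. If sex then caused the autosomal calls, control replicate 1 should lie beyond each mixed control. The amount would be 0.709 to 0.874 of the distance from that control to the Klf5-deleted arrays. Measured along axes from arrays in neither difference, where noise alone gives 0, the ratio averaged −0.059 over all 19106 autosomal genes (6 ratios, −0.16 to −0.00031) and −0.019 over the 221 to 401 genes 2-fold apart on the axis (−0.067 to 0.040), against spreads of 0.112 and 0.104 between arrays of like sex. Pools mix linear signals, however, so for a large fall a mixed pool stays close to a female pool on the log2 scale. Xist read 12.6 in control replicate 1, 12.1 and 11.9 in control replicates 2 and 3, and 5.89 to 6.47 in the Klf5-deleted arrays. Large changes weigh most in these ratios, and most of them were falls. The test therefore does not decide whether sex caused the autosomal calls, and small changes and single genes stay open as well.

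A lower share of epithelium in the Klf5-deleted pools could lower all epithelial genes. The brush border list fell by 0.30 (SE 0.06) more than the pan-epithelial list, a difference of −0.30. The other 10 epithelial lists lay 0.20 to 0.84 above the pan-epithelial list. None of these differences decides the question, since a lower share lowers a list less where its members are also expressed outside the epithelium. Krt19, for one, is in both the pan-epithelial and the mesothelial list. For the pan-epithelial fall itself, a lower share would raise other tissues alike, but of 6 such lists only fibroblasts (0.08, SE 0.03) and mesothelium (0.48, SE 0.14) were higher by over 2 SE, and leukocytes were at −0.09 (SE 0.10). The gap widest in SE of the 15, between mesothelium and leukocytes, was 0.57 (SE 0.13), or 4.36 SE. Mesothelium was added last and may itself have changed. Without it, the gap widest in SE was that between endothelium and leukocytes, at 0.17 (SE 0.07), or 2.60 SE. Both exceed 2 SE, the limit used at the start, which makes no allowance for taking the widest of several gaps. Neither exceeds 6.25, a limit for 15 gaps of a kind set after the 2.60 was seen. These values do not decide whether a lower share caused the pan-epithelial fall.

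Of 3 embryonic globin genes, Hba-x and Hbb-y passed, with calls that were lost on leaving out several arrays, and Hbb-bh1 did not (1.42, adjusted p = 0.0890), values that might come from more blood or younger embryos. Definitive red cell genes shifted less than embryonic globins by 0.64 (a difference of −0.64, SE 0.46), within 2 SE, but the difference was −0.24 (SE 0.41) without Klf5-deleted replicate 1, where definitive genes were higher by 0.63 (SE 0.21), and −1.04 (SE 0.39) without Klf5-deleted replicate 2. The smooth muscle list, which would be lower in younger embryos, shifted by 0.037 (SE 0.03), also within 2 SE (0.061 without Klf5-deleted replicate 1 and 0.0092 without Klf5-deleted replicate 3), so neither is decided and a role of Klf5 stays open. Hsd3b6 read 10.4, 9.87 and 11.8 in Klf5-deleted replicates 1 to 3 and 8.49, 8.26 and 9.36 in the controls, and Hbb-bh1 read 9.01, 8.09 and 9.98 and 7.56, 7.01 and 8.25.

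The 6 arrays can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 3496 genes, 1785 higher and 1711 lower, and 243 with 2-fold, each the result of 1 split, and the highest of the others was 0. Every other split put Klf5-deleted and control arrays together on both sides. The difference between them then widened the spread within each side, which in itself lowers the count of genes. For gene lists, 3 of the 10 splits gave at least the 15 of the real split, and the highest of the others gave 20. That split set Klf5-deleted replicates 1 and 3 with control replicate 1 against the rest.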
